A study of Arabidopsis thaliana with 21 samples.

How the data were processed

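The deposited files hold 1 table per library, 21 in all, with chromosome, position, strand and count; per the file headers the values are counts, and they were checked to be whole numbers on the 5 nuclear chromosomes with no scaling between libraries. Per the submitters' processing notes, adapters were trimmed with cutadapt 1.2.1 and the sequences aligned with STAR 2.5.3a to TAIR10. Which end of the sequence a position marks, how copies of the same sequence were treated and what was done with sequences that map to several places are not stated. Per the labels' protocols, pNET-seq RNA of 35 to 100 nt was recovered after micrococcal nuclease digestion and immunoprecipitation, and GRO-seq libraries were made by poly(A) tailing and circular ligation with 12 to 14 PCR cycles. The replicates' labels do not say whether they come from separate cultures, so the p-values may measure technical spread.

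Genes were taken from a TAIR10.1 name table with gene starts and ends but without strand, exons or sequence. Because TAIR10 and TAIR10.1 bear different names, the table was checked against the files: in all 26 of 26 bins of 5 Mb the counts in protein-coding genes were highest with no shift of the table, and no coordinate is printed. The strand of a gene was called from the files where each assay had at least 20 counts in the gene with at least 70% on the same strand. This gave 22069 of 37887 nuclear genes a strand, 19301 of 27432 among protein-coding genes, and left out 180 genes whose assays gave opposite strands. As a check, 97.2% of 2971 isolated genes had more GRO-seq counts past the called end than before the called start. Strand calls use the same counts as the tests, so genes transcribed on both strands are underrepresented. Sense counts were summed from gene start to gene end. The exon-end index, the exon-to-intron ratio and the part of the position mask that concerns exon ends were not run, because they need exon positions.

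Counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr) in R 4.3.3, with all 12 mock and flavopiridol pNET-seq libraries in 1 fit and all 8 GRO-seq libraries in another, so that the spread was pooled over groups with n = 2. This left 21222 genes in pNET-seq and 20284 in GRO-seq. A gene passed at a Benjamini-Hochberg adjusted p below 0.05. A difference between the antibodies in the response to flavopiridol was tested as an interaction in the same fit. Gene levels are given in CPM, the counts scaled to library size by the cpm function of edgeR with the TMM factors, as mean ± SD, and log2 fold changes as the first named group over the second ± SE, all with n = 2 per group.

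The choices in this paragraph were fixed before the data were examined. There were 15 gene lists: nuclear photosynthesis genes, cytosolic ribosomal proteins, core histones, circadian clock, heat shock, touch and wound response, early auxin response, RNA polymerase II with the kinases and phosphatases of its C-terminal domain (CTD), common reference genes, markers of roots and of guard cells, and the annotated snRNA, snoRNA, tRNA and miRNA genes. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 15 lists of a comparison. Named genes are, per comparison, the 8 protein-coding genes with the largest rise and the 8 with the largest fall among those that passed, that separated the libraries of the groups, that reached 10 CPM in the higher group and that overlap no other gene on the same strand. To these come up to 4 members of each list that passed with the largest change, or the 2 with the highest level where none passed. A gene with over 20% of its counts at 1 position is marked where it is named. For a gene without counts in a group, a fold is given as a lower bound against a floor of 3 counts per library.

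Position along the gene was measured in protein-coding genes of at least 1500 bp with no gene on the same strand within 500 bp and a mean of at least 50 counts in the body, 3750 genes in pNET-seq and 3745 in GRO-seq. The promoter-proximal index of a library is the median over genes of log2 density in the first 200 bp over the body, which runs from 400 bp to 200 bp before the end, with 0.5 added to each sum. The downstream index uses the 500 bp past the gene end in place of the first 200 bp. The flavopiridol effect on an index, averaged over antibodies, was tested by an exact two-sided permutation test with labels exchanged within each antibody, which gives 216 arrangements. With 2 libraries against 2 the smallest possible exact p is 0.33, so effects in a single antibody are given as values. Changes in the share of a gene's counts that fall in the first 200 bp were tested per gene with edgeR in 1 fit of 4 libraries per antibody, as a treatment effect on the first 200 bp relative to the body of the same libraries, and the 5 largest in each direction were named. Density profiles leave out, in each bin along the gene and each library, the 1% of genes with the highest density relative to the body.

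The alternatives were total protein-coding counts as library size without TMM, DESeq2 1.42.0, no filter on low genes, a replicate block, dominant positions left out, genes counted from 300 bp on, only the compared groups fitted, each library left out in turn, wider windows, ratios of sums and a body minimum of 200 counts for the indices. Chosen after seeing the data were snoRNA gene counts as library size, each position counted once, the run-on without sarkosyl against the 22 and 30 °C libraries, and a crossed block. Dominant positions concerned 178 protein-coding genes in pNET-seq and 304 in GRO-seq. Counting, windows and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

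The tests were run on simulated data with changes in 200 genes, as many up as down, at the spread fitted to the data. For flavopiridol and run-on temperature, the changed genes were drawn from those with a mean above 2 CPM. Recovery among genes below that level was not measured. Flavopiridol changed far more genes and its calls depended on the scaling, so the rates of false calls need not hold there. For flavopiridol with the unphosphorylated CTD, 82% of changes of 1 log2 unit and 95% of changes of 2 units were found, with 4.84% false among the calls. For run-on temperature the figures were 78%, 93% and 9.04%, and for the share in the first 200 bp with the unphosphorylated CTD 35%, 76% and 1.77%. Floors and bounds cover counting error only, since copies made by PCR are not independent molecules. The untreated Ser2P library has no replicate and entered no test. Chloroplast and mitochondrial genes were not analysed here.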

Results

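RNA being made was profiled in 12-day-old Arabidopsis seedlings (accession Col-0) in 21 libraries. GRO-seq, in which polymerases engaged on DNA extend their RNA in isolated nuclei, gave 8 libraries, 2 each of a standard run-on, a run-on without sarkosyl, and run-ons at 22 and 30 °C; sarkosyl is a detergent that strips proteins from chromatin. The temperature of the standard run-on and the detergent in the 22 and 30 °C runs are not stated. pNET-seq, which sequences the RNA held by immunoprecipitated RNA polymerase II, gave 13 libraries. They used antibodies against the unphosphorylated CTD of the polymerase (8WG16, here unph), the CTD phosphorylated at serine 2 (CMA602, Ser2P) and at serine 5 (CMA603, Ser5P). Each antibody had 2 libraries of seedlings treated for 1 h with DMSO (mock) and 2 treated for 1 h with flavopiridol, an inhibitor of the cyclin-dependent kinases that phosphorylate the CTD. There was also 1 Ser2P library of untreated seedlings. Total counts per library ranged from 6878913 to 32100845 in GRO-seq, from 20618196 to 26236963 in mock pNET-seq and from 5317441 to 11229835 under flavopiridol, and came to 2447272 in the untreated library. The libraries differed in complexity: the 100 positions with the most counts held 0.397% to 1.15% of the counts in GRO-seq, 2.1% to 3.75% in mock pNET-seq and 4.85% to 15.5% under flavopiridol.

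Polymerase with an unphosphorylated CTD stood close to gene starts, and more so under flavopiridol, whereas in mock libraries polymerase with Ser2P or Ser5P was densest just past gene ends. In mock libraries the unph density peaked 150 bp after the start at 11.2 to 11.7 times the body density, and under flavopiridol at 130 bp and 19.3 to 21.1 times. The Ser5P maximum after the start lay at 270 to 290 bp with 1.45 to 1.54 times the body density in mock libraries and at 170 to 190 bp with 1.84 to 1.91 times under flavopiridol. The Ser2P maximum after the start, at 350 to 490 bp in mock libraries, was 1.5 to 1.52 times the body density, near that of Ser5P, and 1.02 to 1.04 times under flavopiridol. Past the gene end both had a maximum at 50 bp in mock libraries, of 2.54 to 2.72 times with Ser2P and 1.96 to 2.14 times with Ser5P. Under flavopiridol it lay at 10 bp, at 2.6 to 2.79 and 1.8 to 2.14 times. The promoter-proximal index was 1.09 ± 0.0130 with unph in mock libraries and 2.24 ± 0.0226 under flavopiridol (SD, n = 2), -0.94 ± 0.101 and -0.35 ± 0.0290 with Ser5P, and -1.47 ± 0.0580 and -1.63 ± 0.0228 with Ser2P. In every antibody the difference exceeded the spread between the replicates. In GRO-seq the index was -0.27 ± 0.00121 in the standard run-on, 0.25 ± 0.0525 without sarkosyl, -0.09 ± 0.0577 at 22 °C and -0.13 ± 0.0233 at 30 °C (SD, n = 2).

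Within 778 genes of at least 4000 bp, the first 200 bp held 22.8% ± 0.0963 of the unph counts of the first 4000 bp in mock libraries and 32.5% ± 0.360 under flavopiridol (SD, n = 2). The stretch from 400 to 600 bp held 17.5% ± 0.511 and 9.80% ± 0.176, and the stretch from 3000 to 4000 bp 3.02% ± 0.354 and 6.63% ± 0.351. For Ser2P the last stretch held 19.3% ± 0.0960 and 25.9% ± 0.170. Averaged over the antibodies, the promoter-proximal index differed by 0.528 between flavopiridol and mock (exact permutation p = 0.0556), which did not pass 0.05. Because Ser2P moved the other way, this was the smallest p the averaged test could give. The test therefore cannot speak for or against the unph and Ser5P effects alone. With a window of 500 bp and the body from 600 bp the mean difference was 0.00677 (exact p = 0.889), with unph at 0.47, Ser2P at -0.53 and Ser5P at 0.08. The downstream index was -1.94 ± 0.153 and -1.41 ± 0.0201 with unph, -0.47 ± 0.0479 and -0.54 ± 0.0938 with Ser2P, and -0.84 ± 0.136 and -0.94 ± 0.151 with Ser5P, in mock and flavopiridol libraries (SD, n = 2). Its mean difference of 0.118 (exact p = 0.343) did not pass, and as a ratio of sums it was 0.186 (exact p = 0.0370).

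**Figure D1:**
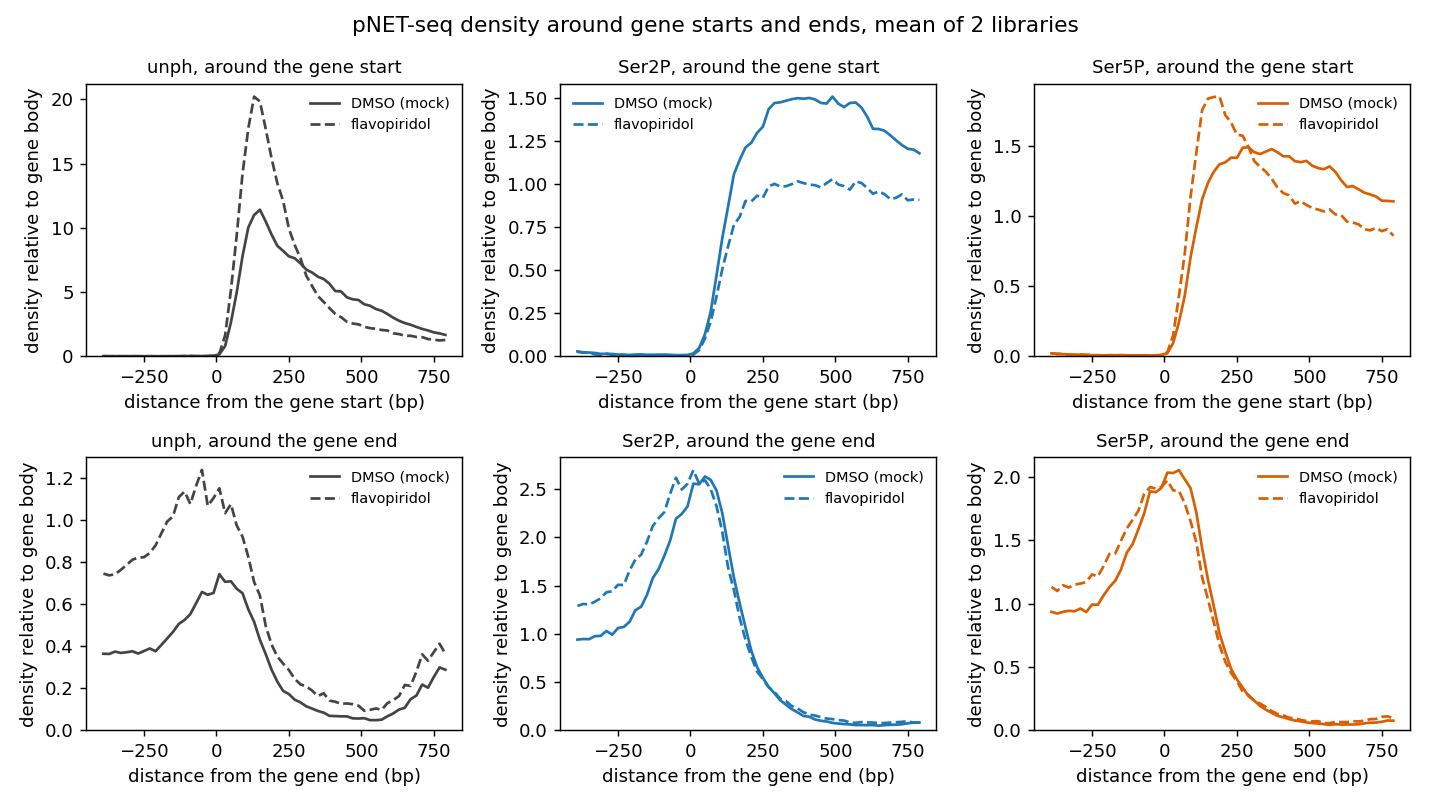
Mean pNET-seq density of 2 libraries, relative to the gene body, against distance in bp from the gene start (top) and end (bottom) for the 3 antibodies; solid lines are DMSO and dashed lines flavopiridol. The unph peak after the start stands at 11.2 to 11.7 times the body density in mock libraries and at 19.3 to 21.1 times under flavopiridol.

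**Figure D2:**
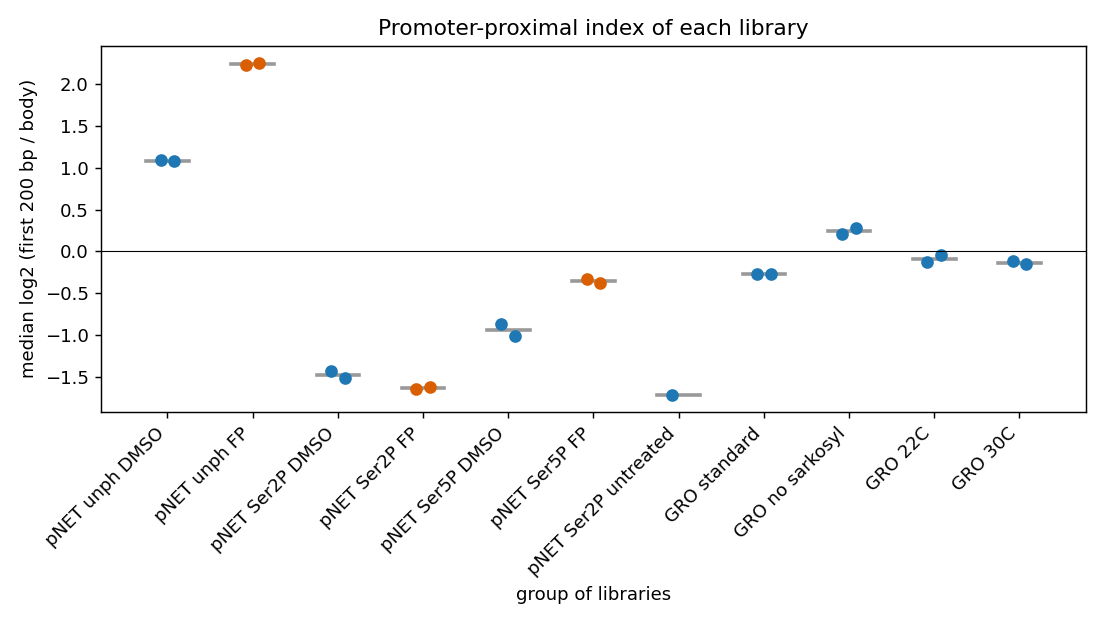
Promoter-proximal index of each of the 21 libraries (points; log2 density in the first 200 bp over the body, median over genes), with flavopiridol libraries in orange and the group mean as a bar. Unph libraries lie at 1.09 under DMSO and 2.24 under flavopiridol, and Ser2P libraries at -1.47 and -1.63.

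Gene by gene, the share of counts in the first 200 bp rose under flavopiridol with unph and Ser5P more often than it fell, at the windows used and at wider ones. Of 3750 genes, 1688 rose and 112 fell with unph, 814 rose and 28 fell with Ser5P, and 41 rose and 138 fell with Ser2P. These counts include genes that passed on 1 library. The share in LHT1 with Ser5P was 1.79% and 0% under flavopiridol and 0% in both mock libraries (edgeR adjusted p = 0.00556). That in AT1G36940 with unph was 0% and 15.8% under flavopiridol and 0% in both mock libraries (edgeR adjusted p = 0.00223). With unph the share in SGT1A (AT4G23570), a co-chaperone of disease resistance proteins, went from 1.13% ± 0.367 to 50.9% ± 0.945 (SD, n = 2; adjusted p = 7.43e-119), that in CBP60G, a regulator of salicylic acid synthesis, from 9.32% ± 2.58 to 82.2% ± 0.850 (adjusted p = 4.98e-125), and that in AT5G41740 from 10.2% ± 0.411 to 85.0% ± 1.99 (adjusted p = 5.87e-214). With Ser5P the share in AT5G41750 went from 0.409% ± 0.176 to 24.4% ± 4.8 (adjusted p = 1.57e-30) and that in AT1G66090 from 3.95% ± 0.594 to 69.3% ± 0.479 (adjusted p = 2.15e-72), while that in ATM, the DNA damage kinase, went from 2.89% ± 0.694 to 0.655% ± 0.0541 (adjusted p = 6.12e-07). With Ser2P the share in AT2G16460 went from 1.98% ± 0.532 to 33.4% ± 2.97 (adjusted p = 1.26e-25) and that in CHR5, a chromatin remodeller, from 1.67% ± 0.286 to 0.131% ± 0.0236 (adjusted p = 5.12e-08). Genes of RNA polymerase II and its CTD kinases rose in 4 of 5 cases with unph (median 2.03) and in 4 of 5 with Ser5P (median 0.99), and in 0 of 5 with Ser2P (edgeR; 587 of all genes were at an unadjusted p below 0.05). Common reference genes rose in 3 of 5 cases with unph and 2 of 5 with Ser5P, photosynthesis genes in 1 of 5 with each of the 2, ribosomal protein genes in 1 of 3 with each (2 of 3 with Ser5P adjusted over the list alone), and auxin genes in 2 of 3 and 1 of 3. No guard cell marker passed among 4 with any antibody. Of the 30 named genes, 16 had no count in the window in 1 of the groups, among them the 5 largest falls with unph, and are given no fold; with the wider windows EXPA5 and CCB1, 2 of these falls, were at 0.89 and 0.53. The wider windows gave 1305 rises and 656 falls with unph, 53 and 1423 with Ser2P, and 629 and 255 with Ser5P. Leaving out 1 library moved several of these counts by over 1.5 times: falls with unph to 65 without mock replicate 1 and 49 without flavopiridol replicate 1, rises with Ser2P to 25 and 26 without mock replicates 1 and 2 and 14 without flavopiridol replicate 2, rises with Ser5P to 443 without flavopiridol replicate 1, and falls with Ser5P to 13 without mock replicate 1 and 13 without flavopiridol replicate 1. Falls with Ser2P were 44 to 87 with 1 library left out in all 4 cases.

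Flavopiridol changed the unph signal on many expressed genes. Heat shock genes lost signal, while clock, touch-response and small nucleolar RNA (snoRNA) genes gained it; with snoRNA counts as library size the clock and touch genes turned lower. FH3 (AT4G15200), a formin, went from 0.398 ± 0.322 to 13.9 ± 3.70 CPM and SERK5, a receptor kinase, from 7.21 ± 0.422 to 124 ± 17 CPM (adjusted p from 2.38e-15 to 4.17e-08). AT3G29000, MYB120, AT2G32340, AT1G72910, AT1G10810 and AT1G72920 were the other 6 of the 8 largest rises among protein-coding genes of at least 10 CPM, with log2 changes of 3.98 to 4.46. The largest falls included RNS1, a ribonuclease, at -5.38 ± 0.443, TIN1, which responds to endoplasmic reticulum stress, at -4.97 ± 0.581, and Hop3, a cofactor of HSP70 and HSP90, at -4.91 ± 0.33 (adjusted p from 8.75e-07 to 0.000319). Of the heat shock genes 2 of 15 rose and 12 fell (median -3.06, or -2.18 with each position counted once). Heat shock genes passed as a set (adjusted p = 0.00109, and adjusted p = 0.332 with an estimated correlation). The chaperone HSP90.1 went from 791 ± 371 to 28.6 ± 0.409 CPM, HSP70 from 1490.0 ± 657 to 80.9 ± 1.36, and the transcription factor HSFA2 from 473 ± 215 to 21.3 ± 0.785. Of the clock genes 7 of 12 rose and 0 fell (8 and 0 adjusted over the list alone, median 1.13, or -0.74 with snoRNA counts as library size). Clock genes passed as a set (adjusted p = 0.00501, and adjusted p = 0.332 with an estimated correlation). The pseudo-response regulators PRR5 and PRR7 rose by 3.34 ± 0.131 and 2.38 ± 0.192, and GI by 2.82 ± 0.147. Of the touch and wound genes 16 of 21 rose and 2 fell (median 1.32, 0.75 with each position counted once, or -0.54 with snoRNA counts as library size). Touch and wound genes passed as a set (adjusted p = 0.000396, and adjusted p = 0.276 with an estimated correlation). The ethylene response factors ERF6 and ERF104 rose by 3.63 ± 0.151 and 2.56 ± 0.188, and the jasmonate repressor JAZ7 by 2.44 ± 0.229.

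Ribosomal protein, photosynthesis, snRNA and snoRNA genes also rose as sets with this antibody, and core histones fell; with snoRNA counts as library size the first 3 turned lower, and with each position counted once the histones turned higher. Of the ribosomal protein genes 14 of 18 rose and 1 fell (median 0.60, or -1.28 with snoRNA counts as library size). Ribosomal protein genes passed as a set (adjusted p = 0.000396, and adjusted p = 0.332 with an estimated correlation). RPL24B rose by 1.30 ± 0.111 and RPL10A by 1.11 ± 0.112. Of the photosynthesis genes 10 of 23 rose and 1 fell (median 0.55, or -1.31 with snoRNA counts as library size). Photosynthesis genes passed as a set (adjusted p = 0.0358, and adjusted p = 0.542 with an estimated correlation). The chlorophyll-binding proteins CAB3 and LHCA1 rose by 3.19 ± 0.423 and 2.52 ± 0.357. Of the snRNA genes 19 of 41 rose and 2 fell (18 and 2 adjusted over the list alone, median 0.93, or -0.95 with snoRNA counts as library size). The snRNA genes passed as a set (adjusted p = 0.00922, and adjusted p = 0.401 with an estimated correlation). One of these spliceosomal RNA genes, U2.2, rose by 3.49 ± 0.369. Of the snoRNA genes 147 of 168 rose and 5 fell (median 1.89, or 0.93 with each position counted once). The snoRNA genes passed as a set (adjusted p = 2.52e-27, and adjusted p = 0.332 with an estimated correlation). In 40 snoRNA genes with counts past the mature end, that stretch changed by -0.78 in the median where the genes changed by 1.93. Together the snoRNA genes held 4.14% ± 0.523 of all counts in mock libraries and 16.0% ± 0.946 under flavopiridol (SD, n = 2). Of the core histones 2 of 17 rose and 12 fell (median -0.65, or 0.29 with each position counted once). Core histones passed as a set (adjusted p = 0.00729, and adjusted p = 0.481 with an estimated correlation). The histone HTA1 changed by -1.34 ± 0.110. The other lists did not pass as sets. Of the reference genes 3 of 12 rose and 8 fell (median -0.41, or 0.20 with each position counted once). GAPC2, a glycolytic enzyme, changed by -1.57 ± 0.152 and UBQ10 by -1.05 ± 0.139. Of the auxin genes 3 of 11 rose and 5 fell (median -0.36, -1.14 in the 10 genes counted from 300 bp, or 0.19 with each position counted once). Of the polymerase and CTD kinase genes 8 of 17 rose and 4 fell (median 0.09, or -1.77 with snoRNA counts as library size). Those that rose included CYCT1;5 and CYCT1;4, cyclins of the kinase that phosphorylates serine 2, at 1.74 ± 0.120 and 1.37 ± 0.131. Of the guard cell markers 1 of 7 rose and 4 fell (median -0.60). Of the root markers 1 of 7 rose and 0 fell (0 and 0 adjusted over the list alone, median 0.14, or -1.73 with snoRNA counts as library size). Of the miRNA genes 25 of 130 rose and 40 fell (23 and 38 adjusted over the list alone, median -0.30, mean 0.06, or 0.01 with each position counted once). Of the tRNA genes 4 of 45 rose and 3 fell (1 and 2 adjusted over the list alone, median 0.88, 0.63 with genes at 0 placed at their bound, or -0.61 with snoRNA counts as library size). In all, 6018 of 21222 genes rose and 6015 fell, 2751 and 2568 of them more than 2-fold (edgeR). With total protein-coding counts as library size, which moved the median of all genes by 0.26, 8079 rose and 3942 fell. With snoRNA counts, which moved it by -1.86, 353 rose and 18635 fell.

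With the Ser2P antibody, flavopiridol raised the signal on photosynthesis, clock and snoRNA genes and lowered it on heat shock, touch and reference genes; with snoRNA counts as library size the clock genes turned lower. Of the photosynthesis genes 17 of 23 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.63). Photosynthesis genes passed as a set (adjusted p = 4.28e-07, and adjusted p = 0.379 with an estimated correlation). CAB3 rose by 3.33 ± 0.450 and LHCB2.1 by 2.40 ± 0.161. Their mock levels were low, at 2.86 and 1.52 CPM for CAB3 and 5.93 and 5.08 for LHCB2.1 (here without TMM factors). Of the clock genes 6 of 12 rose and 1 fell (median 0.68, or -0.58 with snoRNA counts as library size). Clock genes passed as a set (adjusted p = 0.0128, and adjusted p = 0.287 with an estimated correlation). PRR7 rose by 1.95 ± 0.150, GI by 1.81 ± 0.136 and TOC1 by 1.34 ± 0.108. Of the heat shock genes 0 of 15 rose and 12 fell (0 and 13 adjusted over the list alone, median -3.47, or -1.49 with each position counted once). Heat shock genes passed as a set (adjusted p = 1.22e-06, and adjusted p = 0.287 with an estimated correlation). The small heat shock protein HSP17.6A changed by -5.30 ± 0.920, and HSP90.1 went from 752 ± 109.6 to 45.9 ± 16.3 CPM. Of the touch and wound genes 4 of 21 rose and 11 fell (median -0.76, or 0.09 with each position counted once). Touch and wound genes passed as a set (adjusted p = 0.0136, and adjusted p = 0.287 with an estimated correlation). The zinc-finger protein ZAT12 changed by -1.93 ± 0.138, and the cell wall enzyme TCH4 went from 2643 ± 36.4 to 915 ± 88.6 CPM. Of the reference genes 1 of 12 rose and 8 fell (1 and 9 adjusted over the list alone, median -0.49, or 0.21 with each position counted once). Reference genes passed as a set (adjusted p = 0.0136, and adjusted p = 0.287 with an estimated correlation). GAPC1 changed by -1.23 ± 0.136 and the actin ACT7 by -1.04 ± 0.132. Of the snoRNA genes 145 of 168 rose and 1 fell (147 and 2 adjusted over the list alone, median 1.26, or 1.11 with each position counted once). The snoRNA genes passed as a set (adjusted p = 1.29e-25, and adjusted p = 0.287 with an estimated correlation). Past the mature end of 50 of them the median change was 0.10. The snoRNA share of all counts was 3.45% ± 0.0238 in mock libraries and 9.26% ± 1.16 under flavopiridol (SD, n = 2). Of the snRNA genes 14 of 41 rose and 2 fell (median 1.17, -0.21 in the 4 genes counted from 300 bp, or -0.09 with snoRNA counts as library size). The snRNA genes passed as a set (adjusted p = 0.0136, and adjusted p = 0.379 with an estimated correlation). Of the ribosomal protein genes 8 of 18 rose and 0 fell (median 0.21, or -1.03 with snoRNA counts as library size). Ribosomal protein genes passed as a set (adjusted p = 0.0226, and adjusted p = 0.444 with an estimated correlation). RPL5B rose by 0.56 ± 0.113.

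Single genes with large rises in Ser2P included MYB120, a pollen MYB factor, from 1.60 ± 0.491 to 40.9 ± 18.0 CPM, and ADF8, an actin-depolymerising factor, at 3.93 ± 0.178 (adjusted p from 1.48e-12 to 6.62e-07). SEX1, which starts starch breakdown, rose by 3.46 ± 0.324 (adjusted p = 4.66e-05). AT2G31141, also among the 8 largest, has over 20% of its counts at 1 position. The largest falls included the receptor kinase IOS1 at -4.50 ± 0.387, the galactolipid synthase MGDC at -4.33 ± 0.363 and the cytochrome P450 CYP81D8 at -4.16 ± 0.185 (adjusted p from 4.34e-13 to 2.18e-05). The remaining lists did not pass as sets. Of the core histones 0 of 17 rose and 6 fell (0 and 4 adjusted over the list alone, median -0.25, 0.03 with total protein-coding counts, or 0.32 with each position counted once). Of the auxin genes 1 of 11 rose and 5 fell (median -0.64). Of the polymerase and CTD kinase genes 6 of 17 rose and 4 fell (median 0.03, or -1.20 with snoRNA counts as library size). Of the root markers 5 of 7 rose and 0 fell (median 0.54, or -0.70 with snoRNA counts as library size). Of the guard cell markers 3 of 7 rose and 3 fell (4 and 3 adjusted over the list alone, median 0.41, or -0.87 with snoRNA counts as library size). Of the miRNA genes 31 of 130 rose and 23 fell (22 and 17 adjusted over the list alone, median 0.15, -0.15 in the 9 genes counted from 300 bp, or -1.13 with snoRNA counts as library size). Of the tRNA genes 3 of 45 rose and 4 fell (1 and 4 adjusted over the list alone, median -0.05, or 0.23 with total protein-coding counts). In all, 5587 of 21222 genes rose and 5433 fell, 1992 and 2002 of them more than 2-fold (edgeR). With total protein-coding counts as library size, a shift of the median of all genes of 0.28, 8751 rose and 3338 fell. With snoRNA counts, a shift of -1.26, 414 rose and 17568 fell.

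With the Ser5P antibody, photosynthesis, clock and snoRNA genes rose and heat shock and reference genes fell; with snoRNA counts as library size the photosynthesis and clock genes turned lower. Of the photosynthesis genes 15 of 23 rose and 0 fell (median 1.25, or -1.28 with snoRNA counts as library size). Photosynthesis genes passed as a set (adjusted p = 9.63e-06, and adjusted p = 0.423 with an estimated correlation). CAB3 rose by 2.93 ± 0.416 and CAB2 by 2.32 ± 0.281. Of the clock genes 8 of 12 rose and 1 fell (9 and 1 adjusted over the list alone, median 1.07, or -1.43 with snoRNA counts as library size). Clock genes passed as a set (adjusted p = 0.00091, and adjusted p = 0.320 with an estimated correlation). PRR7 rose by 2.2 ± 0.145 and PRR9 by 1.64 ± 0.352. Of the heat shock genes 0 of 15 rose and 8 fell (median -2.13, or -1.34 with each position counted once). Heat shock genes passed as a set (adjusted p = 0.000304, and adjusted p = 0.320 with an estimated correlation). HSP90.1 changed by -2.85 ± 0.476, HSP70 by -2.70 ± 0.410 and HSFA2 by -2.53 ± 0.380. Of the reference genes 1 of 12 rose and 8 fell (median -0.52, or 0.31 with each position counted once). Reference genes passed as a set (adjusted p = 0.0113, and adjusted p = 0.320 with an estimated correlation). GAPC2 changed by -1.15 ± 0.151. Of the snoRNA genes 149 of 168 rose and 2 fell (median 2.53, or 1.28 with each position counted once). The snoRNA genes passed as a set (adjusted p = 3.54e-43, and adjusted p = 0.320 with an estimated correlation). Past the mature end of 49 of them the median change was 0.03. All snoRNA genes held 5.42% ± 0.419 of all counts in mock libraries and 24.7% ± 0.830 under flavopiridol (SD, n = 2). Of the snRNA genes 15 of 41 rose and 2 fell (median 0.60, -0.12 in the 4 genes counted from 300 bp, or -1.88 with snoRNA counts as library size). The snRNA genes passed as a set (adjusted p = 0.0240, and adjusted p = 0.423 with an estimated correlation). Of the ribosomal protein genes 8 of 18 rose and 0 fell (7 and 0 adjusted over the list alone, median 0.25, or -2.28 with snoRNA counts as library size). Ribosomal protein genes passed as a set (adjusted p = 0.0259, and adjusted p = 0.476 with an estimated correlation). Touch and wound genes went both ways, and 6 of 21 rose and 9 fell (median -0.12, mean 0.04, or 0.44 with each position counted once). ERF6 rose by 1.60 ± 0.154 and ERF104 by 1.21 ± 0.189, while the calmodulin-like CML38 changed by -1.11 ± 0.165. Large single changes were those of MYB120 at 3.96 ± 0.358, ADF8 at 3.66 ± 0.192, IOS1 at -3.37 ± 0.363 and ACS8, an enzyme of ethylene synthesis, at -3.06 ± 0.207 (adjusted p from 5.53e-12 to 0.000108). Touch genes and the lists that follow did not pass as sets. Of the core histones 2 of 17 rose and 2 fell (median -0.13, or 0.41 with each position counted once). Of the auxin genes 1 of 11 rose and 4 fell (median 0.07, mean -0.26, and -2.44 as the median with snoRNA counts). Of the polymerase and CTD kinase genes 6 of 17 rose and 3 fell (median 0.23, or -2.30 with snoRNA counts as library size). Of the root markers 4 of 7 rose and 0 fell (5 and 0 adjusted over the list alone, median 0.50, or -2.03 with snoRNA counts as library size). Of the guard cell markers 3 of 7 rose and 2 fell (median 0.20, or -2.31 with snoRNA counts as library size, and -0.08 with each position counted once). Of the miRNA genes 29 of 130 rose and 17 fell (25 and 16 adjusted over the list alone, median 0.26, -0.17 in the 9 genes counted from 300 bp, or -2.23 with snoRNA counts as library size). Of the tRNA genes 3 of 45 rose and 3 fell (1 and 2 adjusted over the list alone, median -0.34, or 0.06 with each position counted once). In all, 5403 of 21222 genes rose and 4405 fell, 1905 and 1356 of them more than 2-fold (edgeR). Without flavopiridol replicate 1, 3552 rose. With total protein-coding counts as library size 4712 rose and 4951 fell. With snoRNA counts as library size, a shift of the median of all genes of -2.52, 34 rose and 20379 fell.

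**Figure D3:**
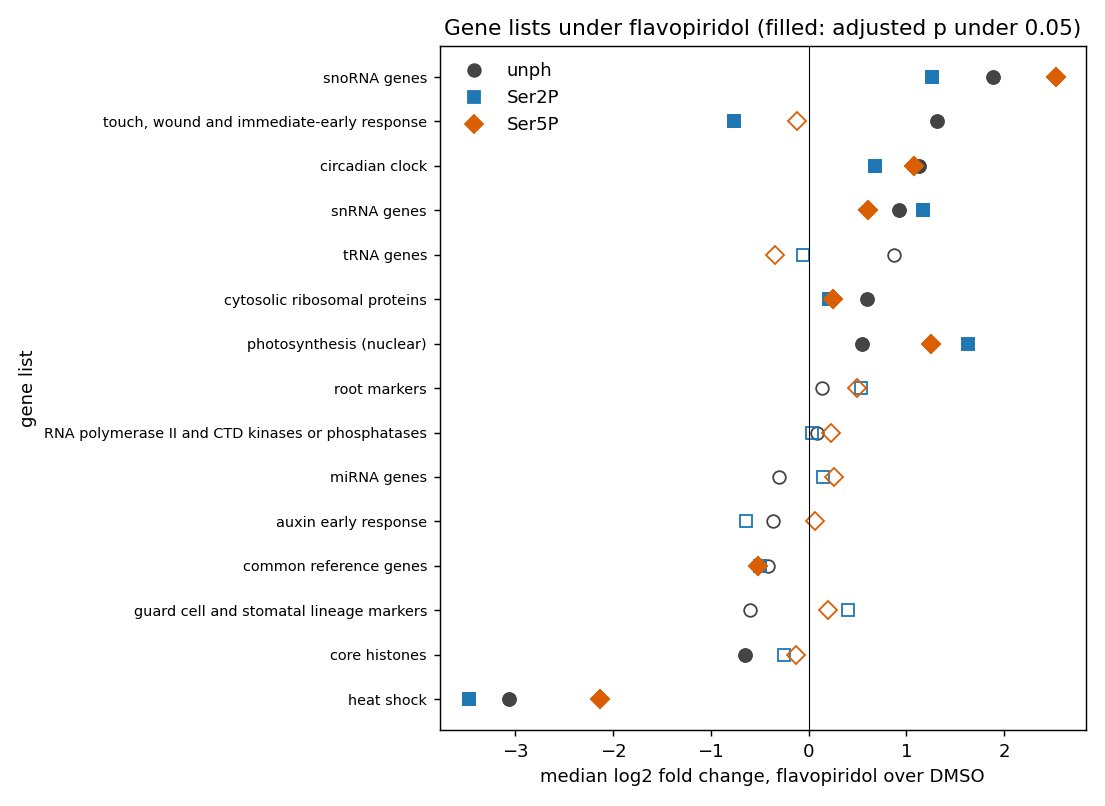
Median log2 fold change, flavopiridol over DMSO, of 15 gene lists (vertical axis) for the 3 antibodies, with filled symbols for an adjusted p below 0.05 at the preset correlation. Heat shock genes lie at -3.06, -3.47 and -2.13 with unph, Ser2P and Ser5P and snoRNA genes at 1.89, 1.26 and 2.53; snoRNA counts as library size shift all genes alike by -1.86, -1.26 and -2.52, so that positive medians smaller than the shift turn negative (8, 7 and 9 of the 15 lists).

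The responses with the 3 antibodies, which share no libraries, overlapped widely and also differed. All 3 antibodies had 2704 genes higher and 2788 lower under flavopiridol, MYB120, PRR7 and CAB3 among the former and HSP90.1, HSP70 and GAPC1 among the latter. Ser2P and Ser5P shared 4177 rises and 3841 falls, against 1422 and 1128 expected if independent; unph shared 3113 rises and 3472 falls with Ser2P (1584 and 1540 expected) and 3246 and 3093 with Ser5P (1532 and 1249 expected). Across genes, which are not independent replicates, the 3 pairs of log2 changes had Spearman's rho of 0.825 for Ser2P and Ser5P, 0.613 for unph and Ser5P and 0.563 for unph and Ser2P (Pearson's r 0.803, 0.632 and 0.581). The response differed between the antibodies in 7004 of 21222 genes (33.0%; edgeR interaction). The difference passed for FH3 (adjusted p = 0.00169), which changed by 5.11 ± 0.384 with unph, and for ERF6 (adjusted p = 2.4e-10), but not for MYB120 (adjusted p = 0.544). Counted from 300 bp the interaction passed in 2809 genes, with each position counted once in 2966, and without unph flavopiridol replicate 1 in 4621. The response rose with gene length: across 18805 protein-coding genes Spearman's rho of length and log2 change was 0.159 with unph, 0.244 with Ser2P and 0.220 with Ser5P, and at the TMM scaling genes of at least 4000 bp had medians of 0.29, 0.38 and 0.41 where those below 1000 bp had -0.20, -0.26 and -0.13.

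The antibodies were compared in mock-treated seedlings to ask where the differently phosphorylated polymerases are found. Relative to other genes, histone, auxin, touch-response, photosynthesis and guard cell genes had lower signal with Ser2P and Ser5P than with unph, and tRNA genes higher signal. The signals come from separate immunoprecipitations scaled by library, so they do not give the amounts of the polymerase forms on a gene. Gene length was not taken into account here, although unph counts lay closer to gene starts. Counted from 300 bp, the Ser2P and Ser5P medians were -1.72 and -1.81 in histone and -1.415 and -1.69 in auxin genes. They were -1.11 and -1.14 in touch, -1.20 and -1.18 in photosynthesis and -0.88 and -1.32 in guard cell genes. All 17 of 17 core histone genes were lower with Ser2P (median -1.54) and all 17 with Ser5P (median -1.51), or -0.91 and -0.92 with each position counted once. The sets passed at adjusted p = 1.43e-07 and 1.25e-06, and at adjusted p = 0.261 and 0.297 with an estimated correlation. AT3G53730, a histone H4 gene, was at -1.71 ± 0.133 and -1.76 ± 0.133. All 11 of 11 auxin genes were lower with Ser2P (median -1.15) and with Ser5P (median -1.28), the repressors IAA1 and IAA2 among them. These sets passed at adjusted p = 0.000777 and 0.00110, and at adjusted p = 0.253 and 0.205 with an estimated correlation. Of the touch and wound genes 0 of 21 were higher and 14 lower (0 and 15 adjusted over the list alone) with Ser2P (median -0.66, -0.30 with total protein-coding counts, or -0.09 with snoRNA counts as library size), and 0 of 21 were higher and 14 lower with Ser5P (median -0.74, or -0.31 with total protein-coding counts). Touch and wound genes passed as sets at adjusted p = 0.00204 and 0.00688, and at adjusted p = 0.231 and 0.205 with an estimated correlation. ERF5 was at -1.50 ± 0.139 and -1.56 ± 0.140. Of the photosynthesis genes 0 of 23 were higher and 13 lower with Ser2P (median -0.89, -0.52 with total protein-coding counts, or -0.32 with snoRNA counts as library size), and 0 of 23 were higher and 13 lower (0 and 12 adjusted over the list alone) with Ser5P (median -0.79, or -0.36 with total protein-coding counts). Photosynthesis genes passed as sets at adjusted p = 0.00260 and 0.00658, and at adjusted p = 0.601 and 0.636 with an estimated correlation. LHCB4.2 was at -1.35 ± 0.133 with Ser2P, and RBCS1B, a Rubisco small subunit, at -1.58 ± 0.150 with Ser5P. Of the guard cell markers 0 of 7 were higher and 6 lower with Ser2P (median -0.72, -0.35 with total protein-coding counts, or -0.15 with snoRNA counts as library size), and 0 of 7 were higher and 7 lower with Ser5P (median -1.13, or -0.70 with total protein-coding counts). Guard cell markers passed as sets at adjusted p = 0.0282 and 0.00735, and at adjusted p = 0.261 and 0.205 with an estimated correlation.

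The tRNA genes, which RNA polymerase III transcribes, were near the limit of counting, the named ones at 0.526 to 2.78 CPM with Ser2P, 0.361 to 2.21 with Ser5P and 0 to 0.028 with unph. Of these, 39 of 45 were higher and 1 lower with Ser2P (median 3.42, 2.79 with genes at 0 placed at their bound), and 34 of 45 were higher and 3 lower with Ser5P (median 2.93, 2.43 with the bounds). With each position counted once the medians were 2.23 and 1.90. As sets they passed at adjusted p = 3.01e-09 and 1.81e-06, and at adjusted p = 0.0103 and 0.0305 with an estimated correlation. AT3G51135 was at least 6.37-fold higher with Ser2P and at least 5.40-fold higher with Ser5P than with unph, where it had no counts. Of the miRNA genes 28 of 130 were higher and 79 lower (29 and 79 adjusted over the list alone) with Ser2P (median -1.24, or 0.80 in the 9 genes counted from 300 bp), and 28 of 130 were higher and 82 lower with Ser5P (median -1.17, or -0.06 in the 9 genes counted from 300 bp). The miRNA genes passed as sets at adjusted p = 0.00623 and 0.00808, and at adjusted p = 0.441 and 0.539 with an estimated correlation. Of the snRNA genes 5 of 41 were higher and 25 lower with Ser2P (median -1.37, or -2.91 in the 4 genes counted from 300 bp), and 14 of 41 were higher and 18 lower with Ser5P (median -0.55, mean 0.00, or a median of -2.34 in those 4 genes). The snRNA genes passed as a set with Ser2P (adjusted p = 0.00204, and adjusted p = 0.263 with an estimated correlation) and did not with Ser5P (adjusted p = 0.734). Of the snoRNA genes 22 of 168 were higher and 91 lower (21 and 91 adjusted over the list alone) with Ser2P (median -0.43, or 0.15 with snoRNA counts as library size), and 61 of 168 were higher and 39 lower (61 and 38 adjusted over the list alone) with Ser5P (median 0.17, or -0.64 with each position counted once). The snoRNA genes passed as a set with Ser2P (adjusted p = 0.00623, and adjusted p = 0.767 with an estimated correlation) and did not with Ser5P (adjusted p = 0.139). Of the heat shock genes 2 of 15 were higher and 6 lower with Ser2P (median -0.47, mean 0.06, or 0.07 with snoRNA counts as library size), and 2 of 15 were higher and 13 lower with Ser5P (median -1.51). Heat shock genes passed as a set with Ser5P (adjusted p = 0.0275, and adjusted p = 0.546 with an estimated correlation) and did not with Ser2P (adjusted p = 0.604). With each position counted once the Ser5P median was -0.89. HSP17.6A was at -2.63 ± 0.469 with Ser5P but HSP18.2 at 4.29 ± 0.354.

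Among clock genes 4 of 12 were higher and 1 lower with Ser2P (median 0.11) and 4 of 12 were higher and 3 lower with Ser5P (median -0.07, mean 0.25, or a median of 0.37 with total protein-coding counts). Counted from 300 bp the medians were 0.73 and 0.57. GI was at 1.77 ± 0.142 and 2.27 ± 0.143, and ELF4, of the evening complex, at -1.60 ± 0.114 and -1.14 ± 0.112. Of the polymerase and CTD kinase genes 8 of 17 were higher and 6 lower with Ser2P (median 0.11) and 8 of 17 were higher and 3 lower with Ser5P (median 0.15), or 0.92 and 1.06 counted from 300 bp. CYCT1;4 was at 1.85 ± 0.123 and 2.00 ± 0.123, and the elongation factor SPT6L at 1.30 ± 0.118 and 1.82 ± 0.119. SPT4-1 was at -1.18 ± 0.155 with Ser2P but at 0.63 counted from 300 bp. Ribosomal protein genes gave 3 of 18 higher and 7 lower (3 and 4 adjusted over the list alone) with Ser2P (median -0.09, mean 0.15, or a median of 0.27 with total protein-coding counts). With Ser5P they gave 6 of 18 higher and 4 lower (4 and 4 adjusted over the list alone, median -0.02, mean 0.21, or a median of 0.41). Counted from 300 bp the ribosomal medians were 0.68 and 0.73. RPS18B, at -0.47 ± 0.107 and -0.35 ± 0.107, was at 1.05 and 1.16 counted from 300 bp, and RPS6A, at -0.40 ± 0.126 with Ser2P, at 0.75. Of the reference genes 3 of 12 were higher and 5 lower with Ser2P and 3 of 12 were higher and 5 lower with Ser5P (medians -0.11 and -0.13, or 0.25 and 0.31 with total protein-coding counts). Of the root markers 0 of 7 were higher and 6 lower (1 and 6 adjusted over the list alone) with Ser2P and 0 of 7 were higher and 6 lower with Ser5P (medians -0.61 and -0.72). Clock, polymerase, ribosomal, reference and root lists did not pass as sets.

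Among protein-coding genes of at least 10 CPM, MYB82, a MYB factor, had a large difference in both comparisons, at 31.8 ± 3.57 CPM with Ser2P and 30.1 ± 2.70 with Ser5P against 0.568 ± 0.162 with unph. NF-YB7, a CCAAT-binding factor, was at 5.34 ± 0.191 with Ser2P (adjusted p = 1.73e-15), and DPBF2, a bZIP factor, at -2.85 ± 0.191 with Ser5P (adjusted p = 1.94e-11). AT1G20320 was at -5.45 ± 0.261 and -3.28 ± 0.202, and AT5G49200, also among the largest falls, has over 20% of its counts at 1 position. In all, 6450 of 21222 genes were higher and 8100 lower with Ser2P, and 7004 higher and 8383 lower with Ser5P (edgeR). The comparisons share the unph libraries, so they are not set against each other. Total protein-coding counts as library size, shifts of the median of all genes of 0.36 and 0.43, gave 9489 and 4941 with Ser2P and 10203 and 5106 with Ser5P. With snoRNA counts, a shift of 0.57 with Ser2P, they were 10564 and 3069 there.

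The run-on without sarkosyl was compared with the standard run-on to see which genes the detergent affects. Heat shock and touch-response genes were lower without sarkosyl, and histone, photosynthesis, miRNA and snRNA genes higher. Most of these differences set the standard libraries apart from the other GRO-seq groups. The standard libraries also held 3.71 and 4.69 counts per position with 18.3% to 23.4% of positions at a single count, against 1.75 to 1.89 and 59.2% to 64.4% in the other 6. Of the heat shock genes 0 of 14 rose and 13 fell (median -3.24). Heat shock genes passed as a set (adjusted p = 3.45e-07, and adjusted p = 0.419 with an estimated correlation). HSFA2 was at 177 ± 41.1 CPM in the standard run-on, 1.07 ± 0.216 without sarkosyl, 1.27 ± 0.796 at 22 °C and 1.16 ± 0.651 at 30 °C (SD, n = 2). Against the 22 and 30 °C libraries, a comparison added after seeing the data, 0 of 14 heat shock genes changed (median -0.107, edgeR, 0 at an unadjusted p below 0.05). Clock genes went both ways, and 6 of 12 rose and 5 fell (7 and 5 adjusted over the list alone, median 1.41, adjusted p = 0.317). GI was at 8.80 ± 0.646 CPM in the standard run-on, 411 ± 12.1 without sarkosyl, 432 ± 42.5 at 22 °C and 441 ± 39.7 at 30 °C. The morning genes LHY and RVE8 changed by -5.22 ± 0.281 and -5.99 ± 0.349 without sarkosyl. Set against the 22 and 30 °C libraries, 0 of 12 clock genes changed (median -0.0687, edgeR, 4 at an unadjusted p below 0.05). Of the touch and wound genes 3 of 20 rose and 16 fell (median -1.22). Touch and wound genes passed as a set (adjusted p = 0.000329, and adjusted p = 0.428 with an estimated correlation). JAZ7 changed by -3.52 ± 0.488 and the WRKY factor WRKY18 by -2.21 ± 0.0956. Relative to the 22 and 30 °C libraries 1 of 20 rose and 0 fell (median 0.0522).

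Gene groups that rose without sarkosyl did so to a smaller extent against the 22 and 30 °C libraries. Of the core histones 16 of 17 rose and 0 fell (median 1.28). Core histones passed as a set (adjusted p = 1.43e-08, and adjusted p = 0.419 with an estimated correlation). AT5G10980 rose by 2.07 ± 0.0955 and AT3G53730 by 2.04 ± 0.0953. Of the snRNA genes 21 of 36 rose and 0 fell (22 and 1 adjusted over the list alone, median 1.96, or 0.89 with each position counted once). The snRNA genes passed as a set (adjusted p = 3.54e-07, and adjusted p = 0.419 with an estimated correlation). U6.6 rose by 5.02 ± 0.179. Of the photosynthesis genes 17 of 23 rose and 4 fell (median 0.79, or 0.36 with each position counted once). Photosynthesis genes passed as a set (adjusted p = 2.21e-05, and adjusted p = 0.469 with an estimated correlation). CAB3 rose by 4.87 ± 0.216 and CAB2 by 4.54 ± 0.120. Of the miRNA genes 35 of 118 rose and 12 fell (34 and 12 adjusted over the list alone, median 0.44). The miRNA genes passed as a set (adjusted p = 0.0297, and adjusted p = 0.419 with an estimated correlation). Against the 22 and 30 °C libraries, 9 of 17 histone genes rose (median 0.44), 12 of 36 snRNA genes (median 0.92), 6 of 23 photosynthesis genes (median 0.19) and 4 of 118 miRNA genes, and of these lists 1 miRNA gene fell. Of the snoRNA genes 39 of 164 rose and 38 fell (median -0.26, mean 0.47). AT4G06250, a snoRNA gene with over 20% of its counts at 1 position, was at least 171-fold higher without sarkosyl. Compared with 22 and 30 °C, 19 of 164 snoRNA genes rose and 0 fell (median 0.51). These and the following lists did not pass as sets. Of the ribosomal protein genes 0 of 18 rose and 8 fell (1 and 8 adjusted over the list alone, median -0.18). Of the auxin genes 2 of 10 rose and 4 fell (2 and 5 adjusted over the list alone, median -0.16, mean 0.14). Of the polymerase and CTD kinase genes 3 of 17 rose and 5 fell (4 and 6 adjusted over the list alone, median -0.03, or 0.05 with total protein-coding counts). Of the reference genes 3 of 12 rose and 3 fell (median 0.01, mean -0.03). Of the root markers 1 of 6 rose and 2 fell (1 and 3 adjusted over the list alone, median -0.73). Of the guard cell markers 1 of 7 rose and 1 fell (median 0.09, mean -0.04, with camera leaning up). Of the tRNA genes 8 of 39 rose and 7 fell (median -0.12, or 0.18 with each position counted once, with camera leaning up). Among the largest rises were LBD24, from 0.305 ± 0.113 to 35.6 ± 0.634 CPM, and PIF4, a light-regulated bHLH factor, from 2.24 ± 0.0802 to 79.3 ± 2.39 (adjusted p from 2.97e-14 to 1.38e-12). HSP90.1 at -7.72 ± 0.762 and Hop3 at -6.66 ± 0.430 were among the largest falls (adjusted p from 0.000122 to 0.00158). AT2G07727 and AT2G07835, in a part of chromosome 2 that is a copy of mitochondrial DNA, were at least 81.7-fold and 49.3-fold higher. The standard libraries had counts in only 14 to 15 of the 24 genes of that copy, and the 22 and 30 °C libraries in all 24. In all, 4542 of 20284 genes rose and 4763 fell, and 538 rose and 80 fell against the 22 and 30 °C libraries. The standard libraries themselves differed from the latter in 5406 genes higher and 5220 lower. With total protein-coding counts as library size 5410 rose and 4108 fell.

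**Figure D4:**
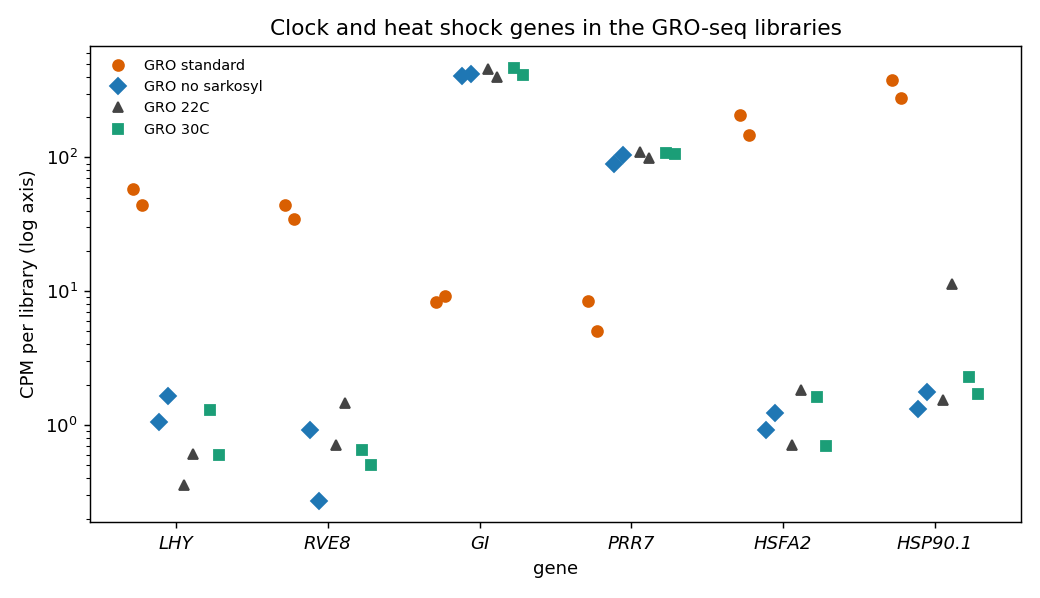
CPM (log axis) of 4 clock genes and 2 heat shock genes in each of the 8 GRO-seq libraries, with a symbol per run-on. GI is at 8.80 CPM in the standard run-on and at 411 to 441 in the other 3 groups, and HSFA2 at 177 against 1.07 to 1.27.

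Run-ons at 30 and 22 °C were compared to see whether the temperature of the reaction alters which genes are read. They gave nearly the same levels: 3 of 20284 genes were higher at 30 °C and 0 lower (edgeR; 452 at an unadjusted p below 0.05; DESeq2 found 4 and 0). AT1G47400 went from 74.1 ± 4.62 CPM at 22 °C to 126 ± 17 at 30 °C (adjusted p = 0.0318) and AT1G13608 from 24.8 ± 1.77 to 44.0 ± 0.821 (adjusted p = 0.0416). AT2G14247, which overlaps another gene and was chosen after its values were seen, went from 69.8 ± 11.3 to 113.9 ± 1.28 (adjusted p = 0.0318). No member of any of the 15 lists passed, adjusted over all genes or over the list alone: the chaperone HSP101 was at -0.78 ± 0.450, the heat shock factor HSFB2A at -0.02 ± 0.134, GI at 0.03 ± 0.0958, TCH4 at 0.00 ± 0.120 and UBQ10 at 0.05 ± 0.0943. As a set the heat shock genes were at -0.25 (adjusted p = 0.0639) and the snoRNA genes at -0.15 (adjusted p = 0.00142, and adjusted p = 0.911 with an estimated correlation), and root markers had a median of 0.00 and a mean of -0.10. With 1 library left out, which leaves 1 in its group, the change of AT1G47400 was 0.61 to 0.90 and that of AT1G13608 0.75 to 0.91. Neither gene passed under every alternative. Replicate 2 of 22 °C stood apart in heat shock genes, with HSP70 at 46.8 CPM against 7.58 in replicate 1 and HSP90.1 at 11.3 against 1.54, and without it HSP101 was at -0.22. With each position counted once 0 genes were higher.

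With an estimated correlation, the tRNA list in the comparisons of Ser2P and of Ser5P with unph was the only set that passed; the other 8, 8, 7, 1, 6, 8 and 7 set calls, in the order flavopiridol with unph, Ser2P and Ser5P, temperature, sarkosyl, Ser2P and Ser5P against unph, did not.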

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

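The test of the touch genes against all genes and counting each position once were tests chosen after the results were seen. The response to flavopiridol differed between the 3 antibodies in 7004 of 21222 genes by the interaction test, which puts a difference between groups on record. The effect on the promoter-proximal index went in opposite directions: Ser2P minus unph was -1.32 and Ser5P minus Ser2P was 0.751, every library of an antibody moving the same way; these differences were not tested.

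The interaction passed in 18 of 21 touch, wound and immediate-early genes, all 18 lower with Ser2P than with unph; the list rose with unph (median 1.32; 16 of 21) and fell with Ser2P (median -0.76; 11 of 21), a difference of -2.08. Counting from 300 bp left a difference of -1.54, which argues against counts in the first 300 bp as the whole cause. Unph signal near the start reached further, so a wider start effect stays open. In genes of at least 4000 bp, the stretch from 400 to 600 bp held 17.5% of mock unph counts of the first 4000 bp, and 9.80% under flavopiridol. A library factor moves all genes alike and so sets where 0 lies for each antibody. The median difference per gene was -1.81 relative to all genes (list quartiles -2.60 and -0.96). No library factor can change that value, so it is no test of scaling. The direction with each antibody does depend on the scaling: with snoRNA counts as library size the list medians were -0.54 with unph and -2.035 with Ser2P. With each position counted once the difference shrank to -0.65 and the Ser2P median turned to 0.09, so copies of the same position, or saturation of well-filled positions, may account for part of the difference and for the fall with Ser2P. The phosphorylation state of the polymerase, which the antibodies select, is the biological explanation the design offers, and it was not tested apart from the antibodies themselves.

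The untreated Ser2P library, a single library of 2447272 counts outside every comparison, is given as values without a test. Its median log2 level over the mock libraries was 5.83 in photosynthesis genes, 0.857 in core histones and 3.14 in clock genes. These 3 lists ranked high among 10000 random lists of genes matched on level (percentiles 100, 99.3 and 100). Heat shock genes, at -1.65, ranked low (percentile 0.67). The level used for matching was the mean of the untreated and mock log2 values, so it held the untreated value itself. Such ranks hold no spread between libraries. All 23 photosynthesis genes were higher than in both mock libraries, at a list median of 2724 CPM (here without TMM factors) against 41.2 and 36.6, as were all 17 histones and 7 of 11 clock genes. CAB2 was at 4644 CPM against 3.75 and 2.23, PRR9 at 163.6 against 1.41 and 0.997, and LUX at 46.3 against 543 and 561. There is no replicate, and treatment, harvest and library were not separated. The untreated library also differed in complexity, with 5.57 counts per position and 29.7% of positions at a single count. The mock Ser2P libraries had 2.87 and 2.74 counts per position and 60.6% and 61.8% at a single count.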

How the results depend on the processing

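The snoRNA scaling, counting each position once, the comparison with the 22 and 30 °C libraries and the crossed block were tests chosen after the results were seen. Of 293 values of counts, indices and lists under all alternatives, these 4 included, 221 kept their direction and side of the threshold where tested, moved by less than the SD of the replicates where not, or, as counts, stayed within 1.5 times. Among the former the mean proximal effect, which did not pass, went from 0.528 to 0.00677 with wider windows. Named genes were tested under the alternatives other than these 4. Of their values, 229 no longer passed and 8 reversed. The other 4957 kept direction and side, or belonged to genes that had not passed and whose sign changed. Genes that passed under each of these alternatives were 62 of 70, 55 of 74 and 63 of 76 for flavopiridol with unph, Ser2P and Ser5P, 0 of 2 for temperature, 56 of 67 for sarkosyl, 64 of 76 and 70 of 76 for Ser2P and Ser5P against unph, and 4, 2 and 4 of 10 for the share. With snoRNA counts, a shift of all genes alike, the signs of 11 of 70, 12 of 74 and 30 of 76 named genes changed (flavopiridol with unph, Ser2P and Ser5P), which follows from the size of the shift, and with each position counted once 6, 11 and 7. Except where given, the cause was not tested. By construction a left-out library leaves 1 in its group, assumed to vary like the others.

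With snoRNA counts as library size, higher and lower genes were 353 and 18635 for flavopiridol with unph, 414 and 17568 with Ser2P, 34 and 20379 with Ser5P, and 10564 and 3069 for Ser2P against unph, and the interaction 17859. With total protein-coding counts 3942 were lower with unph, 8751 higher and 3338 lower with Ser2P, and 4941 and 5106 lower for Ser2P and Ser5P against unph; RPS18B reversed to 0.0840 with Ser5P. Counted from 300 bp the interaction fell to 2809, and reversed were RPS18B (1.05, 1.16), RPS6A (0.75) and SPT4-1 (0.63); with each position once the interaction was 2966 and temperature 0. Only the compared groups gave 5 for temperature. Against 22 and 30 °C, sarkosyl gave 538 and 80.

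With 1 library left out, ranges of higher and lower were 5294 to 6326 and 4021 to 5598 (flavopiridol, unph), 4082 to 4914 and 4344 to 4881 (Ser2P), 3552 to 4664 and 3500 to 3949 (Ser5P; 3552 without flavopiridol replicate 1), 0 to 2 and 0 to 14 (temperature), 3303 to 4747 and 3548 to 4996 (sarkosyl), 5710 to 6995 and 6490 to 7326, and 6343 to 7430 and 6937 to 7704 (Ser2P and Ser5P against unph), and 4621 to 6805 (interaction; 4621 without unph flavopiridol replicate 1). For temperature, 0 were higher without 22 °C replicate 1 (and 14 lower) or 30 °C replicate 1, and 1 without 22 °C replicate 2. AT1G15090, at 1.90, ranged from -0.33 without Ser5P flavopiridol replicate 1, a reversal, to 2.41 without replicate 2. A replicate block, where no label links libraries of the same number, gave 6000 and 5959, 5493 and 5376, 5353 and 4341, 4 and 0, 4544 and 4716, 6421 and 8053, and 6971 and 8339. Deviations between mock replicates correlated at 0.126 for unph and Ser5P, -0.139 for unph and Ser2P and -0.189 for Ser2P and Ser5P. A crossed block, with the numbers of the mock Ser2P libraries exchanged, gave 6551 and 8217 for Ser2P against unph.

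For the share, wider windows gave 656, 1423 and 255 falls (unph, Ser2P, Ser5P), and EXPA5 (0.89) and CCB1 (0.53) reversed. Leaving out 1 library gave 49 to 90 falls with unph, 14 to 44 rises and 44 to 87 falls with Ser2P, and 443 to 721 rises and 13 to 26 falls with Ser5P; the libraries are named in the results. The proximal index effect with unph, Ser2P and Ser5P was 0.47, -0.53 and 0.0781 with wider windows, 1.75, -0.21 and 0.80 as a ratio of sums, 1.30 and 0.71 for unph and Ser5P at 200 body counts, and 1.13 to 1.18 and -0.22 to -0.10 for unph and Ser2P with 1 replicate left out; its mean ranged from 0.484 to 0.573. The downstream effect was 0.37 and -0.16 for unph and Ser2P with wider windows, 0.34, 0.17 and 0.0569 as a ratio of sums (mean 0.186, exact p = 0.0370), and 0.41 to 0.65, -0.17 to 0.0255 and -0.31 to 0.10 with 1 replicate left out (mean 0.0425 to 0.193). Set calls with an estimated correlation went from 8, 8, 7, 1, 6, 9 and 8 to 0, 0, 0, 0, 0, 1 and 1. The exon-end part of the mask, the exon-end index and the exon-to-intron ratio were not run. Depth limits genes near the floor: a floor of 3 counts is 0.170 CPM in mock unph and 0.370 CPM in Ser2P flavopiridol libraries.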

Other observations

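The test of the standard libraries against the other GRO-seq groups and counting each position once were tests chosen after the results were seen. The 24 genes of the copy of mitochondrial DNA on chromosome 2 rose with snoRNA genes as a measured value: together they held 0.0640% to 0.0732% of all counts in mock unph libraries and 0.227% to 0.237% under flavopiridol, 0.0445% to 0.0455% and 0.107% to 0.125% with Ser2P, and 0.0852% to 0.0876% and 0.33% to 0.36% with Ser5P. In GRO-seq 14 to 15 of the 24 genes had a count in the standard libraries and 24 of 24 in the others. Relative to body density, GRO-seq density peaked near the gene end, at -30 to -50 bp and 2.85 to 3.05 times without sarkosyl and at 22 and 30 °C, and at -90 bp and 1.95 to 2.16 times in the standard run-on.

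In the untreated Ser2P library the promoter-proximal index was -1.72 and the downstream index -1.39, against -1.47 and -0.47 in mock Ser2P libraries. Heat shock genes were lower there by list median (-1.65), with 11 of 15 below both mock libraries, and ribosomal protein genes had a median of -1.12, with 16 of 18 below both. The ribosomal median lay only at percentile 6.43 of the random lists. Polymerase and CTD kinase genes were likewise at -1.20, with 16 of 17 below both (percentile 7.31).

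The rise of snoRNA genes under flavopiridol with all 3 antibodies was set against 2 technical explanations. Without positions that hold over 20% of a gene's counts the lowest list median of the 3 antibodies was 1.33, which argues against a few dominant positions. If mature snoRNA carried over with the polymerase takes a larger share of the counts, the 180 bp past the mature end should rise less than the gene: the median of gene minus flank was 2.66 with unph (38 of 40 genes), 1.18 with Ser2P (48 of 50) and 2.56 with Ser5P (45 of 49). Carry-over of mature RNA may therefore explain the rise, in which case part of the scaling shift of other genes would follow. Transcription of snoRNA genes that ends early under flavopiridol, which the treatment groups allow, was not tested.

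The heat shock and clock difference between the run-on without sarkosyl and the standard run-on was set against 2 explanations. With each position counted once the heat shock median was -3.21, which argues against amplification copies. Against the 22 and 30 °C libraries it was -0.107, and the standard libraries stood above the latter by 3.42 with 13 of 14 heat shock genes higher. The standard libraries may thus have been made from seedlings in another state, such as another hour of day, or by another library preparation, given their 3.71 and 4.69 counts per position; the labels give neither. For heat shock and clock genes, a sarkosyl effect of the size found stays open only if the 22 and 30 °C runs lacked it. The labels do not say whether they did. A smaller effect on single genes stays open in either case, as the errors were wide. Against those libraries HSP90.1 was at -1.18 ± 1.29 and LHY at 1.03 ± 0.471 (SE).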
